A study of Xenopus laevis with 6 samples.

How the data were processed

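Gene expression was measured in the dorsal side, cut from the ventral side, of gastrulae of the frog Xenopus laevis. Per the labels, embryos at the 4-cell stage received an injection into each of the 2 dorsal blastomeres of a morpholino oligonucleotide (MO), a synthetic antisense molecule that blocks the translation or splicing of a chosen RNA. The dose was 10 ng of an MO against apcdd1 or of a control MO. Embryos grew at 16 degrees C to stage 10.5, when the dorsal lip of the blastopore is visible, and their dorsal pieces were collected in batches of 10 embryos. There were 3 batches and 3 Affymetrix arrays per group, 6 arrays in all, hybridised with biotin-labelled RNA made from 6 ug of total RNA. The treatment text on the control samples names the apcdd1 MO, while their genotype label names the control MO, and the grouping follows the genotype label. Per the labels, depleted embryos alone were marked ventrally with a dye because some formed the dorsal lip late, so this handling step goes with the group. The labels call the batches separate but do not say whether they came from different clutches, so p-values measure the spread between these batches.

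The values used are the deposited signal intensities of the array table, on a linear scale. MAS5 is named for them in the submitters' processing notes, with no version. The 2% trimmed means of the 6 arrays ran from 171 to 173 and are not one shared target, and the lowest signal per array lay between 3.56 and 3.82, so which summary and scaling made the values stays unsettled. Median signals ran from 44.4 to 45.7. No detection calls and no scan dates were used here. The table holds 32634 probe sets, of which 160 control probe sets were set apart. Of all of them, 15504 carry 1 gene symbol in the platform annotation, 279 carry several and 16851 are unnamed here. The gene number of 15393 of the first kind was found in the RefSeq gene table of assembly Xenopus_laevis_v10.1, which updated 2 symbols. The endings .L and .S mark the homeologs on the long and short chromosomes of this allotetraploid species. No genome was used, so no coordinates are given.

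Signals were raised to at least 1, which moved 0 values, and log2-transformed without further scaling. Probe sets with a mean log2 signal under the 40th percentile over all 6 arrays were left out (4.48, a signal of 22.3), which removed 12990 and left 19484. Of these, 10784 carry 1 symbol, 219 several and 8481 none. Depleted and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and with no fold minimum. Fold changes are differences of mean log2 signal, and signals are means ± SD with n = 3. For arrays, their number limits the precision, and a permutation test of 3 against 3 cannot give a p under 0.1.

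Before the data were examined, 20 gene lists were fixed: organizer, early dorsal Wnt targets, zygotic Wnt targets, BMP and ventral genes, Nodal targets, endoderm, pan-mesoderm, notochord, neural plate, non-neural ectoderm, ventral mesoderm and blood, FGF targets, cell movement, p53 targets and stress response, innate immunity, maternal and germ plasm transcripts, late gastrula to neurula genes, cell cycle, BMP and Wnt antagonists, and reference genes. Of 524 entries, 381 matched by symbol, 41 by a synonym and 102 not at all. Each member was represented by its brightest probe set. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. The camera test asks whether a list moves more than other genes, and fry's directional p asks whether its members move, on balance, one way. Counts of members past the threshold are given over all probe sets and adjusted over the list alone.

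Named genes follow a rule fixed at the same time: apcdd1, then per direction the 12 genes with the largest fold change among probe sets past the threshold whose groups do not overlap and that carry exactly 1 symbol that is not a placeholder, one probe set per gene, and in each list up to 4 members with the lowest p. Had fewer than 6 passed in a direction, the lowest unadjusted p would have filled the places. The methods were tested on simulated data for this comparison with 19484 probe sets and 200 changed. Of the probe sets changed 1.5-fold 59% were recovered and of those changed 2-fold 88%, and 2% of the calls were false. Over 20 draws, every list shifted by -0.2 on the log2 scale was recovered (100%), and 0.71% of unshifted lists were called. The simulated genes vary independently, which real ones do not: the other 9 splits of the real arrays called 0 to 10 of the 20 lists. Alternatives, fixed with the lists, were quantile normalization, median centring, log2 of signal plus 16 or plus 64, no filter and a filter at the 60th percentile, the replicate number as a block, eBayes without trend and robust, array weights, a test per probe set with its own pooled variance, a minimum of 2-fold, all probe sets of each list member, and leaving out each array. Probe sets of one gene can disagree.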

Results

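Signals of 32634 probe sets were recorded for 3 control arrays and 3 arrays of apcdd1-depleted embryos at stage 10.5, cut to their dorsal side, each array from a batch of 10 embryos. Median signals per array ran from 44.4 to 45.7. Apcdd1 is a membrane protein known as an inhibitor of Wnt and BMP signals, and the comparison asks which transcripts of the dorsal gastrula differ when its gene is targeted. Arrays of one group correlated with r between 0.987 and 0.995 for the control and 0.993 and 0.996 for the depleted embryos, against 0.983 to 0.988 between groups, across the tested probe sets of each pair of arrays. The first principal component held 51.1% of the variance and separated the groups, and the second, with 23.8%, separated control batch 1 from control batch 3. The 3' to 5' signal ratio of the gapdh control probe sets, a sign of RNA integrity, was 1.77 ± 0.03 in control and 1.87 ± 0.07 in depleted arrays (SD, n = 3) without overlap. The mean log2 signal of the spiked-in bacterial controls was 10.77 ± 0.15 and 11.02 ± 0.11, with overlap.

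The targeted gene was measured by 1 probe set, of apcdd1.L. Its signal was 308 ± 7.55 in control and 246 ± 15.5 in depleted arrays (SD, n = 3). This is a log2 change of -0.33 ± 0.07 (SE), lower in 3 of 3 depleted arrays, with adjusted p = 0.027 in limma after Benjamini-Hochberg adjustment. A morpholino acts on translation or splicing, so this RNA level does not measure the depletion, and the labels do not say which kind was used. Leaving out single arrays moved limma's adjusted p between 0.049 and 0.094, and it passed the threshold only when control 3 was the array left out.

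Among probe sets with 1 gene symbol, the strongest increases were in foxi1.L, ccng1.L and both homeologs of plk2. foxi1.L, a transcription factor gene of the embryonic ectoderm, rose 13.3-fold, from 54.2 ± 5.65 to 718 ± 30.5 (SD, n = 3; adjusted p = 7.7e-08 in limma). ccng1.L, which encodes cyclin G1 and is a known p53 target, rose 11.1-fold, from 69.4 ± 26.5 to 743 ± 123 (limma adjusted p = 7.0e-04), and its homeolog ccng1.S rose 6.22-fold on its strongest probe set. Both homeologs of plk2, a polo-like kinase gene also known as a p53 target, rose, plk2.S 8.35-fold from a signal of 14.2 ± 0.47 to 119 ± 18.2 and plk2.L 7.38-fold from 15.4 ± 3.77 to 112 ± 15.4. parp3.L, a poly(ADP-ribose) polymerase gene of DNA repair, rose 4.87-fold from 10.6 ± 2.06 to 51.3 ± 7.15. The control signals of plk2.S, plk2.L and parp3.L lie under the filter's signal of 22.3 and were not shown to be above background, so the sizes of these folds are uncertain. Further increases were in marchf8.L, a ubiquitin ligase gene (4.01-fold, and 2.19-fold on its other probe set), ptn.L, which encodes the growth factor pleiotrophin (3.97-fold), the Ras-like GTPase gene rasl11b.L (3.46-fold, to 1677 ± 104) and the histone H2B gene h2bc11.S (3.19-fold, to 4149 ± 176).

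Among probe sets with 1 gene symbol, the largest decrease was in sds.L, encoding serine dehydratase. It was 3.85-fold lower, from 85.5 ± 9.45 to 23.1 ± 7.53 (SD, n = 3; limma adjusted p = 0.0035), where depleted array 1, at 14.4, is under the filter's signal, so the size of this fold is uncertain too. tat.S, encoding tyrosine aminotransferase, was 3.27-fold lower, and pnp.L, encoding purine nucleoside phosphorylase, 3.28-fold lower, from 325 ± 36.5 to 99.0 ± 7.27 (limma adjusted p = 1.9e-05). The amino acid transporter gene slc38a2.L was 2.54-fold lower on one probe set and 1.89-fold lower on the other. The thioredoxin-related gene tmx4.L was 2.97-fold lower, eif1ad.L 2.67-fold, the DNA helicase gene blm.S 2.65-fold, reep5.L 2.51-fold, the carbonic anhydrase gene ca14.L 2.48-fold, rdh10.L, which encodes a retinol dehydrogenase, 2.33-fold, and ttc5.L 2.25-fold. For both reep5 and rdh10 the S homeolog differed by less than the test could call, with log2 changes of -0.01 ± 0.10 and 0.04 ± 0.08 (SE).

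Among the 12 genes per direction, 3 with several probe sets had only the strongest one past the threshold. The increase of anxa5.S, an annexin gene, was on 1 of its 5 probe sets (7.27-fold, from 29.1 to 212), while the brightest stood at 829 ± 20.1 and 817 ± 70.6. The cold-inducible RNA-binding gene cirbp.L rose 4.29-fold on a dim probe set, while its bright one was at 8393 ± 263 and 7960 ± 317 (SD, n = 3). Of its homeolog cirbp.S, 1 probe set was called higher (log2 change 0.55 ± 0.10 SE, adjusted p = 0.0096 in limma). The other cirbp.S probe sets did not pass, with -0.22 ± 0.06 on the brightest. hnrnpu.L, an RNA-binding protein gene, was 2.71-fold lower on its dimmest probe set. Its other probe sets went the same way by less, with log2 changes of -0.21 ± 0.12 and -0.22 ± 0.06 (SE). The homeolog hnrnpu.S was called lower (-0.25 ± 0.06, adjusted p = 0.037 in limma). For ccng1.S, its other probe sets gave log2 changes of 0.84 ± 0.07 and 0.24 ± 0.09, the latter not past the threshold. Unnamed probe sets also changed strongly: Xl2.32009.1.S1_at was 29.4-fold and Xl2.54072.1.S1_at 10.6-fold higher, and Xl2.13895.1.A1_at was 3.77-fold and Xl2.24337.1.S1_at 3.41-fold lower. The control signal of Xl2.32009.1.S1_at, 28.8 ± 9.77, is near the filter's signal of 22.3, so the size of its fold is uncertain. The depleted signals of Xl2.13895.1.A1_at and Xl2.24337.1.S1_at, 12.2 ± 1.56 and 17.1 ± 4.88, are under the filter's signal.

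**Figure D1:**
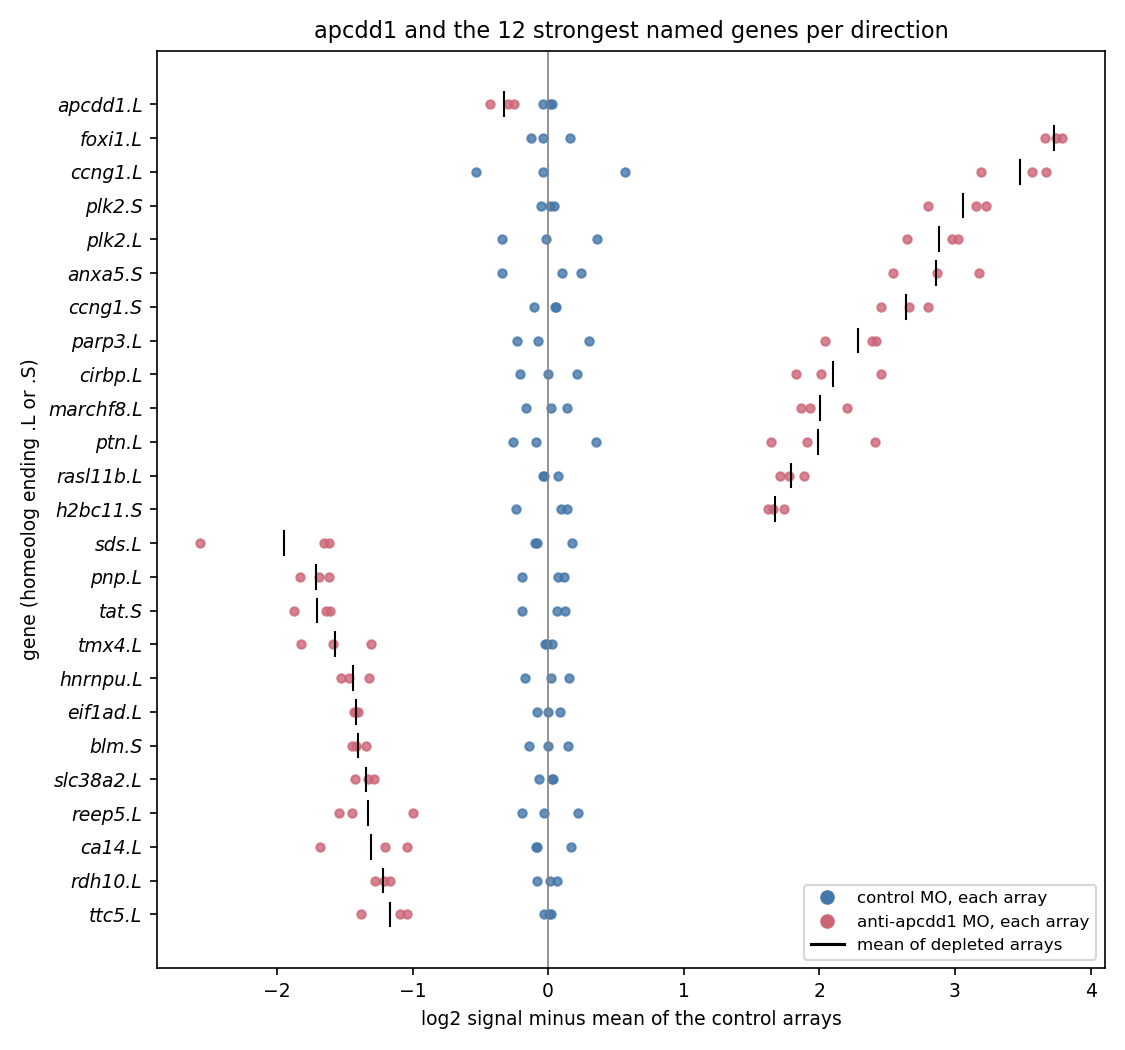
Log2 signal of each array minus the mean of the control arrays (horizontal axis) for apcdd1.L and the 12 strongest named genes per direction (vertical axis), with a point per array and a bar at the mean of the 3 depleted arrays. Groups that do not overlap were part of the rule that picked the 12 genes per direction, and those of apcdd1.L do not overlap either. The mean changes run from -1.95 for sds.L to 3.73 for foxi1.L.

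Across the 19484 tested probe sets, 1289 (6.62%) passed the threshold in limma, 585 higher and 704 lower in depleted embryos. At least 2-fold changes were called for 81 probe sets upward and 57 downward, and at least 4-fold changes for 24, all upward. The named calls with 1 symbol cover 679 genes, 303 with a higher and 379 with a lower probe set, so 3 genes have both. The 3 depleted arrays all lay above or all below the 3 control arrays in 4820 probe sets, 24.7% of those tested, against 10% by chance. The count depends on the batches and on the weighting: it was 669 without control 2, 739 without depleted 3, 4449 with array weights and 196 when each probe set was tested with its own variance alone.

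Genes of the Spemann organizer, the dorsal signalling centre of the gastrula, were lower as a list. Of 27 measured members, 7 fell, 1 rose and 19 did not pass the test, and 26 of the 27 had a negative log2 change, with a median of -0.20. chrd.1.S, which encodes the BMP antagonist chordin, fell from 2267 ± 145 to 1539 ± 179 (SD, n = 3; limma adjusted p = 0.0046). admp.S, a BMP-family ligand gene of the organizer, fell from 1200 ± 118 to 867 ± 40.1 and otx2.S, an anterior homeobox gene, from 349 ± 21.4 to 233 ± 17.8. The member that rose was sfrp2.S, which encodes a secreted Wnt antagonist, from 404 ± 2.23 to 601 ± 67.0. Adjusted over the list alone, 10 fell and 1 rose. The camera test gave adjusted p = 1.3e-06, and adjusted p = 0.21 with an estimated correlation. The lists overlap, and 24 of the 27 organizer members stand in another list too. The gapdh 3' to 5' ratio, 1.87 ± 0.07 against 1.77 ± 0.03, differed between the same arrays for all of the lists.

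Notochord, pan-mesoderm and neural plate genes were lower as lists in the same camera test. Of 18 notochord members, 3 fell, chrd.1.S, admp.S and tbxt.L, the gene of the mesodermal T-box factor Brachyury (532 ± 28.4 to 366 ± 49.8), and bix1.3.L rose (adjusted p = 0.0075, and adjusted p = 0.21 with an estimated correlation). bix1.3.L entered the notochord list through the synonym bix4 and stands in the endoderm and Nodal lists too. Of 23 pan-mesoderm members, 6 fell and 2 rose (adjusted p = 0.0041, and adjusted p = 0.24 with an estimated correlation). fgf3.L, a fibroblast growth factor gene, fell from 208 ± 13.8 to 94.0 ± 1.53, tbxt.2.S from 53.1 ± 6.76 to 28.7 ± 2.95, and cyp26a1.S, encoding an enzyme that degrades retinoic acid, from 304 ± 18.9 to 216 ± 15.8, with a log2 change of -0.25 on another probe set that did not pass. aplnr.L, the apelin receptor gene, went the other way, from 374 ± 28.5 to 1051 ± 93.1 (log2 change 1.49 ± 0.08 SE, limma adjusted p = 1.6e-05), as did wnt11b.L. Of 25 neural plate members 7 fell and 0 rose (adjusted p = 1.0e-04, and adjusted p = 0.21 with an estimated correlation). They include otx2.S, foxb1.S (89.2 ± 4.73 to 55.7 ± 9.84), pou3f2.S (28.1 ± 4.03 to 18.7 ± 0.55, under the filter's signal) and sall1.L (1822 ± 162 to 1319 ± 128), although another probe set of sall1.L did not pass (adjusted p = 0.63 in limma). One more probe set, left out as dim, was called higher in the fit without the filter, from 11.9 ± 1.15 to 26.6 ± 4.65 (SD, n = 3; limma adjusted p = 0.0010). Adjusted over the list alone, 4, 9 and 9 members fell and 2, 2 and 0 rose in these 3 lists.

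Zygotic Wnt targets were also lower as a list, with 5 of 23 members lower and 1 higher (median -0.16). The camera test gave adjusted p = 0.0075, and adjusted p = 0.24 with an estimated correlation. cdx1.S, a posterior homeobox gene, fell from 82.6 ± 5.53 to 53.1 ± 6.48 and mespa.L, a mesodermal transcription factor gene, from 60.5 ± 8.62 to 39.4 ± 5.19 (SD, n = 3). The member that rose was ventx1.2.S, and apcdd1.L itself is one of the members that fell. Adjusted over the list alone, 9 fell and 1 rose. Without the dimmer probe sets under the 60th percentile, the calls of this list and of pan-mesoderm ended, with adjusted p = 0.43 and 0.16.

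Of 6 measured ventx genes, homeobox repressors induced by BMP on the ventral side and grouped here after their values were seen, 3 rose. ventx1.2.S rose from 179 ± 3.73 to 265 ± 19.2, ventx2.1.S from 991 ± 85.0 to 1370 ± 74.5 and ventx2.1.L from 1115 ± 76.9 to 1379 ± 14.6 (SD, n = 3; limma adjusted p = 0.0022, 0.0047 and 0.016). The others did not pass and had negative log2 changes, -0.24 ± 0.11 for ventx3.2.S, -0.09 ± 0.11 for ventx1.1.S and -0.01 ± 0.08 for ventx1.1.L (SE). The 3 that rose were the only called members of the ventral mesoderm and blood list, where 3 of 11 members rose and 0 fell (4 and 0 adjusted over the list alone). This list did not pass camera (median 0.06, adjusted p = 0.062). In the BMP and ventral list 4 of 31 members rose and 2 fell (7 and 2 adjusted over the list alone), among them gata3.S, lower from 91.3 ± 2.26 to 56.99 ± 9.50, and the list did not pass (adjusted p = 0.27). In the list of BMP and Wnt antagonists 5 of 26 fell and 1 rose (5 and 3 adjusted over the list alone), namely fst.L, the follistatin gene, chrd.1.S, admp.S, frzb.L and apcdd1.L against sfrp2.S. It did not pass either (adjusted p = 0.14).

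p53 targets and stress response genes were higher as a list, with a median log2 change of 0.12. Of 28 measured members, 6 rose, 2 fell and 20 did not pass the test, and adjusted over the list alone 7 rose and 2 fell. The camera test gave adjusted p = 0.0019, and adjusted p = 0.30 with an estimated correlation. Beside both ccng1 homeologs, the sestrin genes sesn2.S and sesn1.L rose from 141 ± 11.5 to 261 ± 15.7 and from 130 ± 2.73 to 204 ± 10.9 (SD, n = 3; limma adjusted p = 3.1e-04 and 8.9e-04). gadd45a.S and ddit4.S, both genes of stress responses, rose too, and ccng2.L, a cyclin G2 gene, and hspa1l.S, a heat shock protein gene, fell. The innate immunity list did not pass (median 0.09, adjusted p = 0.38). Of its 12 measured members nfkbia.L rose and socs1.S fell, and the counts adjusted over the list alone were 1 and 1.

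Maternal and germ plasm transcripts were lower as a list, with 7 of 42 members lower and 1, wnt11b.L, higher. Adjusted over the list alone, 11 fell and 3 rose. The median was -0.07, and the camera test gave adjusted p = 0.0091, and adjusted p = 0.61 with an estimated correlation. wee2.L, a cell cycle kinase gene of the egg, fell from 1192 ± 21.2 to 795 ± 100 and the germ cell genes dazl.L and grip2.L from 499 ± 5.56 to 315 ± 57.9 and from 496 ± 65.4 to 250 ± 49.5 (SD, n = 3). The call ended without control 1 (adjusted p = 0.081) and without depleted 2 (0.18). The reference genes were lower as well, with 2 of 19 lower, 0 higher and a median of -0.09. Their camera test gave adjusted p = 0.0049, and adjusted p = 0.24 with an estimated correlation, and adjusted over the list alone 5 fell and 0 rose. The members that fell were the ribosomal protein genes rpl13a.L (853 ± 57.4 to 606 ± 56.4) and rps2.L (2329 ± 92.0 to 1993 ± 60.6).

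The remaining lists did not pass camera and held called members in both directions or few of them. In non-neural ectoderm 4 of 26 members rose and 1 fell (also adjusted over the list alone): foxi1.L, the epidermal grainyhead genes grhl3.L and grhl1.L and foxi4.2.S rose, and gata3.S fell. None of the 3 other probe sets of foxi4.2.S passed. Its median was 0.01 with adjusted p = 0.27. In the cell cycle list 3 of 53 members rose, pcna.S, pcna.L and orc1.L, genes of DNA replication, and 4 fell, both homeologs of the cyclin gene ccne2 and of the phosphatase gene cdc25a (7 and 7 adjusted over the list alone, adjusted p = 0.59). pcna.L rose from 2249 ± 135 to 2918 ± 206 and ccne2.S fell from 630 ± 103 to 345 ± 33.2 (SD, n = 3). In endoderm 1 of 27 members rose and 4 fell (3 and 7 adjusted over the list alone, adjusted p = 0.28), among them gata6.S, an endodermal transcription factor gene, from 386 ± 30.8 to 213 ± 14.6. Nodal targets had 3 of 29 members lower and 1 higher (4 and 2 adjusted over the list alone, adjusted p = 0.14). The strongest of them, mxi1.L, entered through a synonym and encodes a partner of MAX rather than a Nodal target. The movement list had 2 of 37 members higher and 1 lower (2 and 2 adjusted over the list alone, adjusted p = 0.39). The homeologs of prickle1, a planar polarity gene, were called in opposite directions, prickle1.L lower (1399 ± 17.9 to 894 ± 41.6) and prickle1.S higher (1543 ± 74.2 to 1859 ± 45.8). FGF targets had 4 of 24 lower, fgf3.L, dusp1.L, tbxt.L and dusp5.S, and 0 higher (4 and 0 adjusted over the list alone). Their median was 0.00 and their mean -0.11 (adjusted p = 0.38). Early dorsal Wnt targets had 1 of 11 lower, hhex.L, whose other probe set had a log2 change of -0.04 and did not pass, and 0 higher (1 and 0 adjusted over the list alone, adjusted p = 0.76). Late gastrula to neurula genes had 1 of 5 lower, the muscle gene myod1.L, and 0 higher (1 and 0 adjusted over the list alone, adjusted p = 0.50). In 5 list members, chosen after their values were seen, the brightest probe set was not called while another was: bmp4.S (log2 change -0.72 on the called one), gata4.S (-0.31), rnd1.L (-0.63) and rrm1.L (-0.89) were lower there and pax3.L (0.75) higher. Other probe sets of sox2.L, grip2.L and rps2.L, and 1 of gadd45a.S, did not pass beside a called one.

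**Figure D2:**
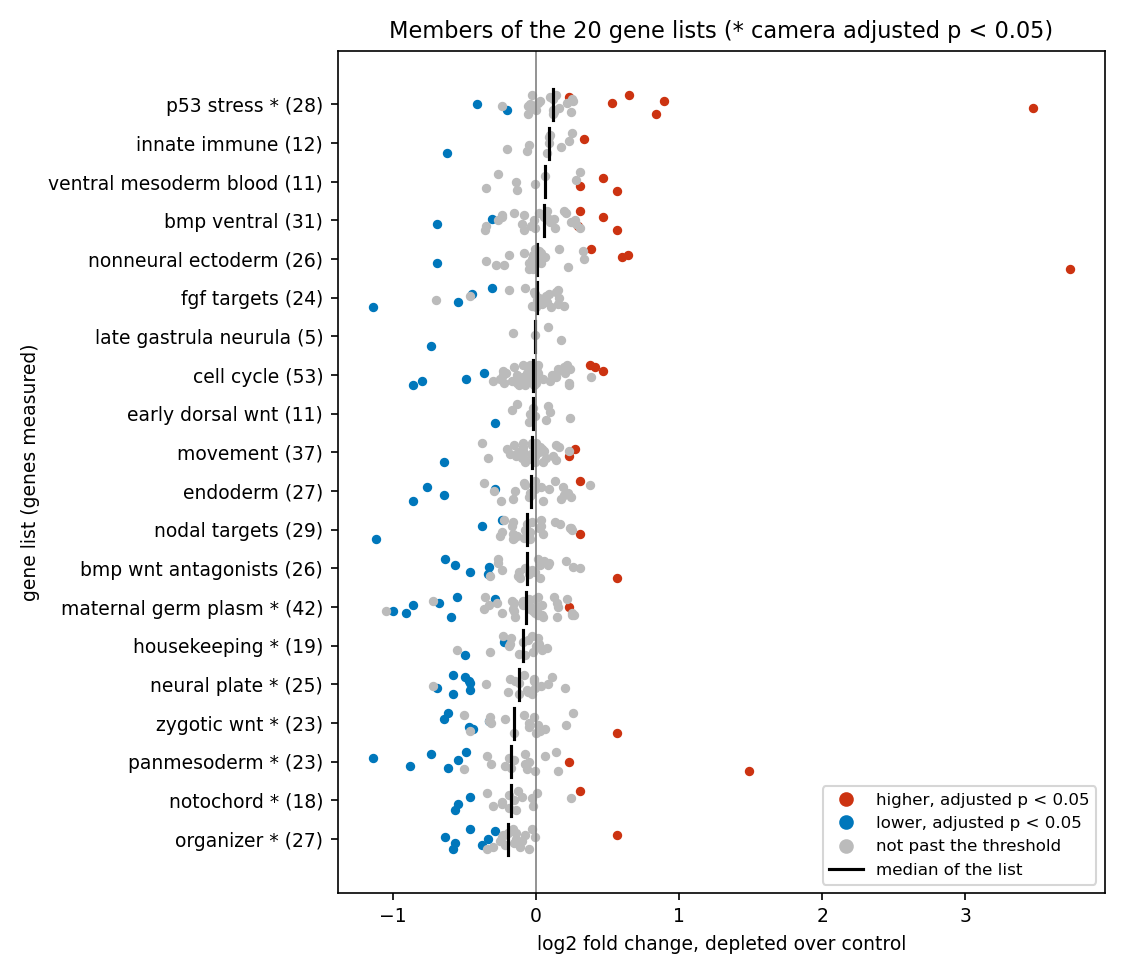
Log2 fold change of depleted over control (horizontal axis) for each measured member of the 20 gene lists (vertical axis, number of members in parentheses), coloured by whether the gene passed the limma threshold, with a bar at the list's median and an asterisk where camera's adjusted p was under 0.05. Medians run from -0.20 for the organizer to 0.12 for p53 and stress genes, and 8 lists carry an asterisk, of which 0 pass with an estimated correlation.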

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

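Probe sets left out as dim were fitted in the alternative without the filter, a signal outside the main measurement. Among the 12990 left out, 61 were higher and 42 lower in depleted embryos at the threshold, 6 and 2 of them at least 2-fold. Of those with a symbol, some were chosen after their values were seen. cdkn1a.L, the gene of the cell cycle inhibitor p21 and a known p53 target, had a signal of 7.04 ± 1.46 in control and 11.4 ± 0.96 in depleted arrays (SD, n = 3; limma adjusted p = 0.015). runx1.L, a blood transcription factor gene, had 15.6 ± 0.26 and 26.4 ± 3.21 (limma adjusted p = 0.0041). tbx6r.L, a T-box gene, had 14.2 ± 1.03 and 26.5 ± 5.04. All of these probe sets lie under the filter's mean log2 signal of 4.48.

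The 3' to 5' ratio of the gapdh control probe sets, which enter no comparison of genes, was 1.87 ± 0.07 in depleted and 1.77 ± 0.03 in control arrays (SD, n = 3), with the groups 0.0081 apart. The ratio of the actin control probe sets was 2.49 ± 0.14 and 2.44 ± 0.12, with overlap.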

How the results depend on the processing

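With quantile normalization, median centring, either added constant, no filter, the stricter filter and eBayes without trend and robust, the number of probe sets past the threshold stayed between 944 and 1320, and between 917 and 1285 of the 1289 calls were shared, with the same sign. Array weights gave 4449, with 2046 higher and 2403 lower, a test with each probe set's own pooled variance gave 196 and a 2-fold minimum 138; the cause was not tested. Leaving out one array gave 669 to 1430 in all, 305 to 610 higher and 364 to 820 lower, lowest without control 2. For apcdd1.L these fits gave log2 changes of -0.36 to -0.27. Same-numbered arrays had deviations correlated at 0.05, 0.02 and -0.27, so no pairing by number was seen. With 3 arrays per group these values cannot show whether the numbers mark shared clutches. With the replicate number as a block, 1101 probe sets passed, and the call of apcdd1.L ended (log2 change -0.33, adjusted p = 0.061 in limma).

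With an estimated correlation, the 8 list calls ended at unchanged medians: organizer -0.20, notochord -0.17, neural plate -0.12, zygotic Wnt -0.16, pan-mesoderm -0.17, p53 and stress 0.12, maternal -0.067, and reference genes -0.091. Their adjusted p ran from 0.21 to 0.61. With fry, non-neural ectoderm (median 0.0078) and ventral mesoderm and blood (0.062) passed and the maternal list (-0.067) did not. With the 60th percentile filter, zygotic Wnt (-0.050) and pan-mesoderm (-0.077) did not pass and ventral mesoderm and blood (0.31) did, over fewer genes. Early dorsal Wnt targets, never called, turned direction with array weights (0.032) and with all probe sets of each member (0.033), and without control 1 or depleted 2. Leaving out one array at a time, its median ran from -0.14 to 0.084, that of Nodal targets from -0.10 to -0.039, endoderm from -0.088 to 0.017, ventral mesoderm and blood from 0.021 to 0.13, BMP and Wnt antagonists from -0.083 to -0.012 and the maternal list from -0.11 to -0.055. These last 5 lists changed sides of the threshold in some of these fits, and the other 7 calls kept theirs in each. The log2 change of neurog2.S, not called, ran from -0.024 to 0.16. Of the 86 named genes, the fits without one array ended between 5 calls (without control 3) and 17 (without control 2); the replicate block ended 8, and 9 ended without trend and robust. The named genes whose call ended in at least one fit without an array are apcdd1.L, hhex.L, sall1.L, mespa.L, ventx2.1.L, lefty.S, bix1.3.L, gdf3.S, tbxt.L, pou3f2.S, grhl1.L, dusp1.L, dusp5.S, prickle1.S, wnt11b.L, socs1.S, nfkbia.L, myod1.L, fst.L and rps2.L, with adjusted p up to 0.19. Dim signals limit what could be called, since 12990 probe sets lay under the filter.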

Other observations

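Histone genes, a family chosen after their values were seen, are a further group. Of 19 measured histone genes 6 rose and 0 fell in depleted embryos, under quantile normalization and median centring too. Beside h2bc11.S they are h1-6.L, a linker histone gene (704 ± 266 to 1874 ± 175), h2ac14.L (94.0 ± 9.33 to 234 ± 32.0), h2ax.S (413 ± 69.8 to 808 ± 121), h2ax.lS and h2ac7.L (198 ± 22.1 to 318 ± 15.8; SD, n = 3). The other members kept the family's median at 0.00. Camera gave adjusted p = 0.020 over 4 such families, and adjusted p = 0.19 with an estimated correlation.

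Of 85 ribosomal protein and protein-like genes, each by its brightest probe set, 5 fell, among them rpl35a.S and rpl7a.S, and 0 rose. Their median was -0.06 (camera adjusted p = 0.020, and adjusted p = 0.85 with an estimated correlation). A dimmer probe set of rps27.S was called higher (log2 change 1.23, adjusted p = 3.5e-04 in limma). Proteasome genes had 3 of 56 higher and 4 lower, with both homeologs of psmd9 lower and psmd14.S higher (adjusted p = 0.28 in camera). Of 7 keratin genes 0 were called (adjusted p = 0.85 in camera). The last 3 families were chosen after values were seen too, and all of these counts were the same under both scalings.

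The tests of the patterns below were chosen after the results were seen, except the counts of splits. The 6 arrays can be split 10 ways, too few for a share under 0.05. The real split gave 1289 probe sets and the highest of the others 0, so 1 of the 10 splits gave as many. Every other split mixes control and depleted arrays, so the group difference widens its spread and lowers its count. The 0 therefore does not show what arrays without a group difference would give. For lists past the camera threshold the real split gave 8 and the highest of the others 10, for controls 1 and 3 with depleted 3 against the rest, so 2 of the 10 splits gave as many. Over the other 9 splits the lists past the threshold numbered 6, 2, 5, 5, 2, 10, 4, 7 and 0, far above the 0.71% of unshifted lists called in simulated data, although these splits still hold part of the group difference.

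The p53 and stress genes were higher as a list in camera at its preset correlation, with 6 of 28 members called higher and 2 lower. With an estimated correlation this call was lost (adjusted p = 0.30). Scaling between arrays as the sole cause of the 6 calls is argued against by their range. They changed by 0.23 ± 0.05 (ddit4.S) to 3.48 ± 0.27 (ccng1.L, log2, SE), more apart than one offset allows. The reference genes had a median of -0.09. All 6 of 6 stayed higher under both scalings, but these moved little, so that count tests little. The spiked-in controls were 0.25 higher in depleted arrays on the log2 scale, with overlap. A small offset in the list's median of 0.12 or in ddit4.S is therefore not excluded. A single misassigned probe set is argued against for gadd45a.S, ccng1.S and sesn1.L. Of 7 other probe sets of the called genes and their homeologs, 4 were also called higher, all of them in these genes. Among the 4, Xl2.1519.3.S1_at of gadd45a.S shares its name up to the ending with the member's own probe set and may not be independent. Xl2.47781.1.A1_at of gadd45a.S (log2 change 0.28) and Xl2.55582.2.S1_at of ccng1.S (0.24) did not pass. The one of sesn2.L did not pass (log2 change 0.12, adjusted p = 0.26 in limma). ddit4.S had no other tested probe set, so its assignment was not checked. An innate immune response to the injected oligonucleotide stays open, because the median of that list was 0.089 (95% bootstrap interval -0.056 to 0.20, 12 members). A general p53 response to injection of this oligonucleotide and a response to loss of apcdd1 itself may both give this pattern and were not tested apart, since one anti-apcdd1 MO and no rescue were analysed here.

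Organizer, notochord, pan-mesoderm and neural plate genes were lower in camera at its preset correlation, and with an estimated one these calls were lost (adjusted p = 0.21 to 0.24). Scaling between arrays as the sole cause of the called members' changes is argued against by their range. Their log2 changes ran from -1.14 ± 0.08 (SE) for fgf3.L to 1.49 ± 0.08 for aplnr.L, where one offset would move all alike. These are extremes of genes picked as called, so they do not bear on the smaller list medians, -0.12 to -0.20. A small offset in those medians is not excluded, since the reference genes were lower as a list too. Of the 19 members called lower, 19 lie more than 2 SE under the reference genes' median of -0.09. That count follows largely from their being called, so it is no evidence on scaling. More ventral tissue in the depleted dorsal pieces stays open: the ventral mesoderm and blood list had a median of 0.062 (95% bootstrap interval -0.14 to 0.31). Of its 11 members 8 stand in another list too, and the 3 called ones were ventx genes, which BMP induces. It therefore cannot tell more ventral tissue from stronger BMP signals. Slower development, which the labels mention for the dorsal lip, could raise maternal transcripts, and that list had a median of -0.067 (-0.17 to 0.0037), which does not decide it. Loss of apcdd1, the biological difference of the design, also remains open. Loss of a Wnt inhibitor alone would raise zygotic Wnt targets, and their median was -0.16, apcdd1.L included (camera adjusted p = 0.0075, 0.24 with an estimated correlation, and 0.43 at a median of -0.050 with the 60th percentile filter). Of these 23 members 16 had negative and 7 positive log2 changes, and 17 stand in another list too. Members differed: axin2.L (0.26 ± 0.26 SE), axin2.S (0.02 ± 0.13) and notum.L (0.03 ± 0.09) did not pass, and sp5.L fell (-0.44 ± 0.11). The median therefore does not settle whether Wnt signalling changed.

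Probe sets of one gene disagreed in 8 of the 18 genes that had several tested probe sets and at least one called 2-fold, in that another probe set changed by under 1.2-fold. They are hnrnpu.L, rps27.S, cirbp.L, anxa5.S, ccng1.S, post.L, pclaf.S and rassf7.L, of which rps27.S, post.L, pclaf.S and rassf7.L lie outside the rule for named genes and were chosen after their values were seen. Scaling between arrays moves the probe sets of a gene nearly alike, so one offset would not give log2 changes of 2.86 and -0.03 in anxa5.S. In 8 of the 8 genes the probe sets differed by more than 2 SE. The genes were chosen for such a difference, so this count tests nothing further. That in 0 of the 8 the 2-fold probe set was the brighter one, in the group where it was lower, depends on the change itself and compares signals of different probes, so a role of dim probe sets may exist or not. The dimmer probe sets of genes with several were called 2-fold no more often than probe sets of similar signal from genes with 1, with 17 of 2568 against 20.8 predicted (p = 0.83, one-sided binomial test).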
